A study of Homo sapiens with 538 samples.

How the data were processed

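RNA of the NCI-60 panel (60 established human tumour cell lines in RPMI-1640 with fetal bovine serum, per the labels) was measured on Affymetrix arrays after 2, 6 and 24 h with 0, 10 or 100 nM paclitaxel in DMSO. Per the labels, RNA was isolated with Qiagen RNeasy kits, its quality was read on a Caliper LabChip, and it was labelled with biotin with an Affymetrix HT One-Cycle kit. The labels gave 1 array per cell line, dose and time, no replicate numbers, batches or scan dates. The 538 arrays were placed in 9 groups by dose and time, and the tissue of each line was taken from the labels. The combinations of HL-60 at 100 nM and 24 h and of NCI-H522 at 10 nM and 2 h had no array.

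The deposited table gives values on what its range and quantiles show to be a log2 scale, already normalized between arrays by the authors, and the labels state neither the log base nor the method of summary and normalization. Values ran from 2.81 to 14.37 and array lower quartiles from 3.93 to 4.24. Detection calls were not used here, so the signal over background is unknown. Of 22277 probe sets, 62 were controls, 2108 had no gene and 1043 several genes in the platform annotation, and these were left out of the tests by gene. The 19064 probe sets with 1 gene, 19052 of them matched to current gene names by Entrez identifier, gave 11963 genes, each represented by the probe set with the highest mean over all arrays. All 538 arrays were nearest to another array of their own line, and 0 arrays were identical. Upper quartiles and the 3' to 5' difference of beta-actin were used to find 25 arrays over 6 median absolute deviations from the median of their line. XIST and genes on the Y chromosome were kept in the tests but are never named, which left 24 genes out of the naming.

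For each line the log2 difference between treated and control array of the same time was computed, so that cell line was the block. Mean differences were tested with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with moderated t tests whose prior variance followed the gene mean, and Benjamini-Hochberg adjustment with a threshold of 0.05. A second count took differences of at least 0.5. The comparisons were each dose against 0 nM at each time, 100 against 10 nM, the difference of responses between consecutive times, 24 against 2 h at 0 nM, tissues with at least 6 lines (limma F test) and leukemia against other lines. Error values are the moderated SE unless SD is named.

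The 22 pathway lists and 6 lists of cell type markers were written from general knowledge of the drug and panel. They were tested with camera of limma (preset correlation 0.01) on the differences with all genes as background, with adjustment over the 22 lists within each of the 6 dose comparisons (the 6 marker lists formed their own family). Beside it stand camera with an estimated correlation and a sign-flip permutation of the list mean per line with 1e+05 resamples. Tissue differences of list means used 1e+05 permutations of the tissue labels. Relations with baseline levels used Pearson r and Spearman rho over lines with 100000 permutations, adjusted over each family. The tests of explanations used 8 relations as their own family. Members rose or fell when they passed limma over all genes, and counts adjusted over the list alone are named so.

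Genes were named by rule. At 24 h these were the 10 highest and 10 lowest differences among genes past the test that changed the same way in at least 75% of lines, and at 2 and 6 h the 5 highest and 5 lowest. For comparisons of doses, of times, of culture time and of leukemia lines they were the 5 highest and 5 lowest past the test, for tissues the 10 smallest p, and for each list at 6 and 24 h the 4 members past the test with the smallest p. ABCB1, TUBB3, MAPT and CDKN1A were read in every dose comparison. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

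The limma step was tested on simulated data with 200 changed genes of 11963. Changes of 0.5 and 1 were recovered in 100% of genes in all 6 dose comparisons. Changes of 0.2 were recovered in 98% and 100% (10 and 100 nM) at 2 h, 100% and 100% at 6 h and 86% and 98% at 24 h. Changes of 0.1 were recovered in 38% and 62%, 58% and 64%, and 58% and 32% in the same order, with 10, 7, 16, 7, 1 and 3 false calls. A G2/M list shifted by -0.2 at 100 nM and 24 h was recovered, and camera also called 8 of the 21 other lists. In 50 sets of unchanged data, camera with the preset correlation called a mean of 0.28, 0.44, 0.78, 1.06, 4.72 and 4.86 of 22 lists in the same order of comparisons, against at most 0.06 with an estimated correlation and 0.1 with sign flips.

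Alternatives were quantile normalization, median centring, the mean of probe sets, the 33.3% of genes with the lowest means left out, robust eBayes, a rank test, no replicate block, arrayWeights, no leukemia lines, no lines of shared origin (NCI-ADR-RES, MDA-MB-435 and U251 left out), all groups in one fit, an adjusted p under 0.01 and leaving out each line in turn. Chosen after seeing the data were fits without the 25 low-quality arrays and fits with the bacterial hybridisation controls and the beta-actin difference as covariates. Lists were also tested with an estimated correlation and sign flips. Relations were recomputed without the 2 lines farthest from the median of the baseline level, with tissue means removed, and with response size as the number of genes that differ by at least 1. The agreement of doses was recomputed with no shared controls. For each count 100 random splits were drawn, with treated and control swapped within lines or tissue labels permuted.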

Results

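The series asked how the transcriptome of the NCI-60 panel, 60 established human tumour cell lines from 9 tissues, changes over time after an anticancer drug. The drug here was paclitaxel, which binds beta-tubulin and stabilises microtubules. Affymetrix arrays measured RNA at 0, 10 and 100 nM paclitaxel after 2, 6 and 24 h, in 538 arrays and 9 groups with 1 array per cell line, dose and time. Each group held 60 lines, except 59 at 100 nM and 24 h (without HL-60) and 59 at 10 nM and 2 h (without NCI-H522). The lines were the replicates, and the 0 nM array of the same line and time was the control, so no line had replicates of its own. The panel held 9 lung, 9 melanoma, 8 renal, 7 colon, 7 ovarian, 6 breast, 6 leukemia, 6 CNS and 2 prostate lines. Deposited signals ran from 2.81 to 14.37 with array medians of 4.95 to 5.43. The values gave 11963 genes, and no coordinates are given because no genome build is named with the values. Differences are on the log2 scale of the deposited signals, as means over lines ± SE.

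The first question was what 24 h of 100 nM paclitaxel changes. The genes that rose the most were stress and immediate early transcription factors, a chemokine and H2B histones. ATF3 rose by 1.09 ± 0.13 (higher in 51 of 59 lines, adjusted p = 2.43e-09), EGR1 by 1.09 ± 0.17 (48 of 59), the interleukin-8 gene CXCL8 by 1.06 ± 0.18 (49 of 59) and the H2B gene H2BC5 by 1.09 ± 0.16 (46 of 59). The other H2B genes H2BC12L, H2BC21, H2BC12 and H2BC6 rose by 0.87 to 1.00. H2BC5, H2BC12L and H2BC6 were read by probe sets ending in _x_at and H2BC21 by a set ending in _s_at, while H2BC12 had a plain _at set. Sets of the first 2 kinds can match several transcripts. The H2B values, here and below, are therefore not shown to be separate rises of each gene. GTF2H2B, a copy of a subunit gene of transcription factor TFIIH, rose by 0.98 ± 0.11 and the trafficking gene TRAPPC10 by 0.90 ± 0.11. The genes that fell the most included several of the cell cycle. FBXO5, which encodes the anaphase-promoting complex inhibitor EMI1, had a difference of -1.20 ± 0.15 (lower in 53 of 59 lines), the cyclin gene CCNE2 -1.13 ± 0.15 (51 of 59), the replication checkpoint gene TOPBP1 -1.03 ± 0.13 (54 of 59) and the mitotic kinase gene CDK1 -0.98 ± 0.15 (51 of 59). The pocket protein gene RBL1 followed with -0.99, the nucleoside transporter gene SLC29A1 with -0.94 and the RNA-binding gene RBM23 with -0.87. The chromatin gene VPS72 had -0.81, the ubiquitin-conjugating enzyme gene UBE2C -0.79 and the centromere gene CENPC -0.75. In limma, 3830 of 11963 genes changed, 1806 higher and 2024 lower, and 86 of them by at least 0.5 (33 higher, 53 lower). The larger side turned with the scaling, with 2055 higher and 1821 lower after quantile normalization and 2263 and 1735 after median centring. Of 95 genes, those named by rule for this comparison together with TOP2A and MTCL2, 35 have several probe sets. For 0 of them did another probe set change in the opposite direction by over 2 SE. This finds reversals only and passes sets without a change. KIF5B, for example, had 0.17 on its named set and 0.033 on the other. SMAD6 had -0.255 on its named set and -0.056, -0.021 and -0.030 on the others. The other added names were not part of this check.

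**Figure D1:**
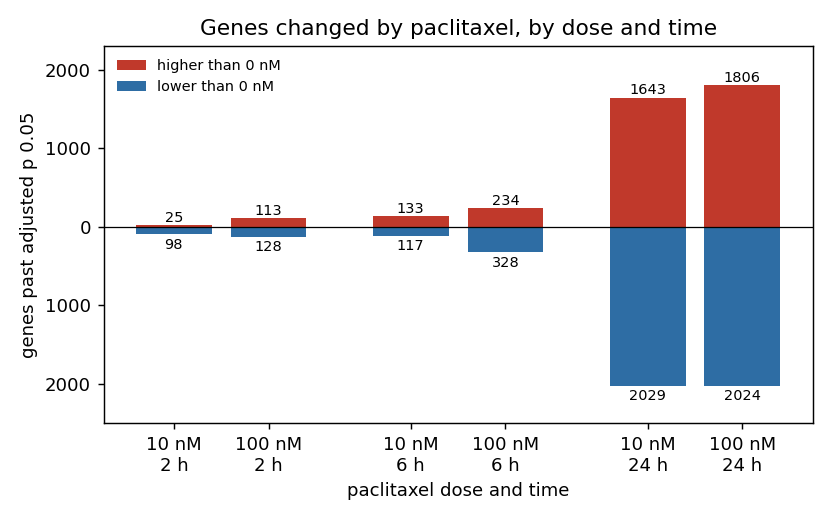
Bars give the number of genes past an adjusted p of 0.05 against 0 nM (higher above the line, lower below it) by paclitaxel dose (nM) and time (h). The bars total 123 and 241 genes at 2 h and 3672 and 3830 at 24 h for 10 and 100 nM, with 234 higher and 328 lower at 100 nM and 6 h.

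At 100 nM and 24 h, most genes of mitosis rose and those of DNA replication fell. In the list of G2/M and mitosis genes (36 of 37 members tested, the others here and below having no probe set for that gene alone, mean 0.22, SD 0.42 over lines, higher in 41 of 59 lines), 28 rose and 5 fell, or 30 and 5 adjusted over the list alone. CKS2 rose by 0.40 (52 of 59 lines), the anaphase activator gene CDC20 by 0.51 (51 of 59), the mitotic kinase gene AURKA by 0.57 (50 of 59) and the securin gene PTTG1 by 0.37, while CDK1 and UBE2C fell as above. The other members that fell, TOP2A by 0.36, NUSAP1 by 0.28 and CDC25C by 0.26, were chosen after their values were seen, as were the members added below to complete counts of 5 or fewer. The list of G1/S and DNA replication genes (33 of 35 tested) fell by 0.41 in the mean and was higher in 6 of 59 lines. In it 32 members fell and 1 rose (ORC6 by 0.11, an added name), and the same numbers held adjusted over the list alone. The helicase genes MCM4 and MCM3 fell by 0.61 and 0.52, the primase gene PRIM1 by 0.63 and the chromatin assembly gene CHAF1B by 0.49. Replication histones (13 of 20 tested, mean 0.49, SD 0.65, higher in 45 of 59 lines) held 10 members that rose and 1 that fell (H1-4 by 0.20, an added name), also adjusted over the list alone. Not every histone probe set rose. The set with the highest level (10.14), which several H4 genes share and the list leaves out, had a difference of -1.04. It was above 0 in 8 of 59 lines. Of all sets, 28 of 41 with names ending in a plain _at, 7 of 8 in _s_at and 12 of 14 in _x_at had means above 0. Camera with the preset correlation gave an adjusted p of 2.27e-12 for G2/M, 2.78e-25 for G1/S and 6e-05 for histones. With an estimated correlation, the adjusted p was 0.298 for G2/M, 0.172 for G1/S and 0.298 for histones, so none of these calls held. The sign-flip permutation test over lines gave adjusted p values of 0.000489, 7.33e-05 and 7.33e-05.

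**Figure D2:**
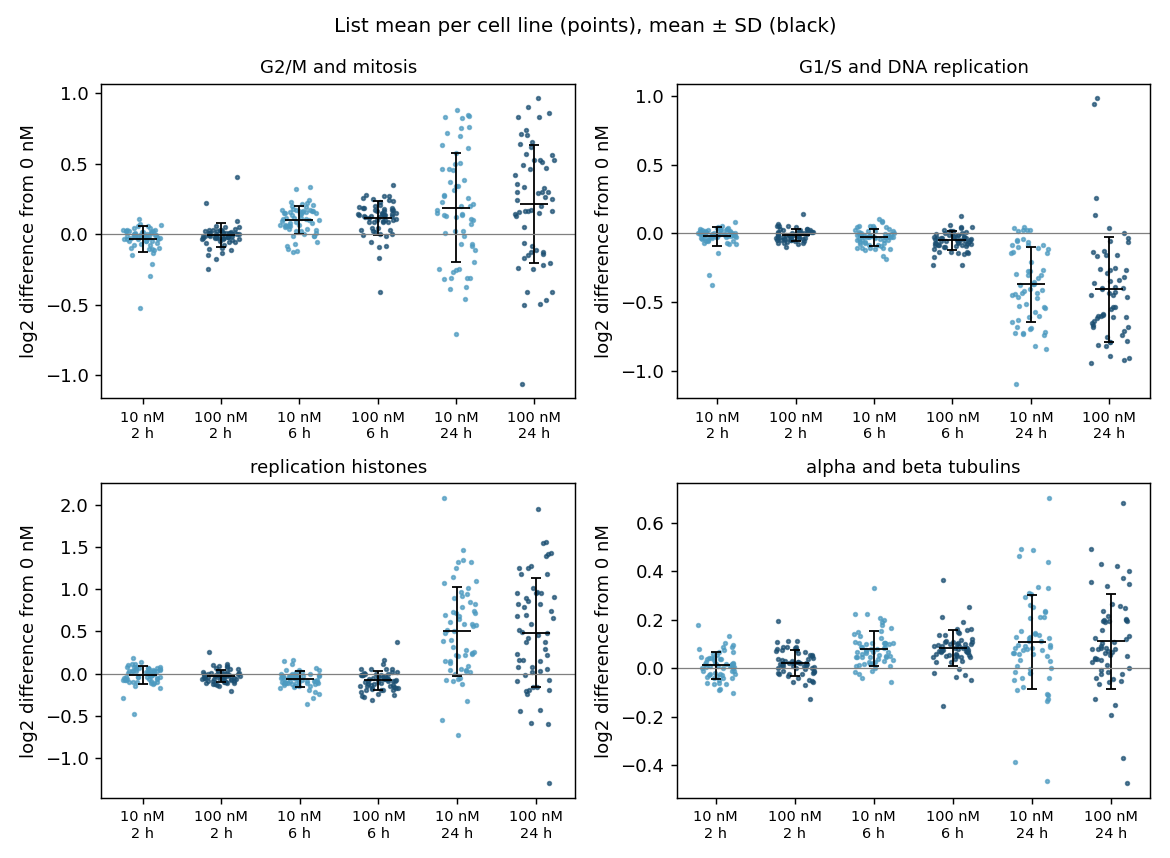
Each point is the mean log2 difference from 0 nM of a gene list in 1 cell line, by dose (nM) and time (h), with the mean and SD over lines in black. At 100 nM and 24 h, the G2/M and mitosis mean was above 0 in 41 of 59 lines and the G1/S and DNA replication mean in 6 of 59.

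Genes of the drug's target changed as well at 100 nM and 24 h. Among alpha and beta tubulins (13 of 14 tested, mean 0.11, higher in 44 of 59 lines), 6 members rose and 1 fell, also adjusted over the list alone. TUBB2A rose by 0.51 (54 of 59), TUBA4A by 0.24, TUBB4B by 0.18 and the beta-III tubulin gene TUBB3 by 0.185 ± 0.03 (45 of 59, adjusted p = 1.11e-05), while TUBB, an added name, fell by 0.12. The probe sets of TUBB3 (0.195 and 0.185) and TUBB4B (0.189 and 0.176) all end in _x_at and can match several transcripts. The TUBB3 values, here and below, are therefore not shown to come from that gene alone. Genes of gamma, delta and epsilon tubulins and of the gamma-tubulin complex (7 of 8 tested, mean -0.091) held 4 members that fell, TUBGCP4 by 0.20 (lower in 49 of 59 lines), TUBGCP2 and TUBGCP5 by 0.14 and TUBG2 by 0.10, and 5 adjusted over the list alone. Camera gave adjusted p = 0.0175 for both lists, against adjusted p = 0.367 with an estimated correlation for alpha and beta tubulins and 0.298 for the other list. The efflux pump gene ABCB1 (-0.018, adjusted p = 0.777) and the tau gene MAPT (-0.086, adjusted p = 0.114) did not pass the test.

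Stress and signalling genes changed in the same comparison. Immediate early genes (22 of 23 tested, mean 0.27, higher in 46 of 59 lines) held 13 members that rose and 2 that fell (14 and 3 adjusted over the list alone), with FOSL1 up by 0.60 and FOS by 0.72. The 2 that fell, added names, were JUND by 0.73 and MYC by 0.26. NF-kappaB and cytokine genes (20 of 23 tested, mean 0.24, 41 of 59 lines) held 13 that rose and 1 that fell, also adjusted over the list alone, with IL11 up by 0.63, CCL20 by 0.38 and RELB by 0.25, while the inhibitor gene NFKBIA, an added name, fell by 0.24. Targets of p53 (19 of 26 tested, mean 0.15, 35 of 59 lines) held 11 that rose and 1 that fell, BAX, also adjusted over the list alone. The cell cycle inhibitor gene CDKN1A rose by 0.37 ± 0.08 (44 of 59, adjusted p = 0.000123), the DNA damage gene GADD45A by 0.44, the death receptor gene FAS by 0.35, the nuclease gene AEN by 0.30 and TRIAP1 by 0.17. Cholesterol synthesis genes (10 of 16 tested, mean -0.145) held 6 that fell, or 8 adjusted over the list alone, among them DHCR7 by 0.26 (50 of 59 lines), LSS by 0.22, MVD by 0.19 and IDI1 by 0.13. Camera gave adjusted p = 0.000131 for immediate early genes, 8.24e-05 for NF-kappaB, 0.0014 for p53 targets and 0.00183 for cholesterol synthesis. With an estimated correlation, adjusted p was 0.298, 0.298, 0.388 and 0.367 in the same order, so none held. The sign-flip permutation test gave adjusted p values from 7.33e-05 to 0.00088 for these 4 lists.

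The remaining lists did not pass camera at 100 nM and 24 h, although single members changed. Among ATF4 and unfolded protein response genes (adjusted p = 0.0762, 6 rose and 3 fell), DDIT3 rose by 0.59, PPP1R15A by 0.43 and the serine synthesis gene PSAT1 fell by 0.57. Heat shock proteins (0.0655) held BAG3 with 0.32 and HSPH1 with 0.20, and the spindle checkpoint list (0.0655, 7 rose and 2 fell) held MAD2L1 with 0.23, BUB1 with 0.37 and MAD2L1BP with 0.15. The BCL2 family (0.382, 5 rose and 2 fell) held the pro-apoptotic gene PMAIP1 with 0.32, BAK1 with 0.195 and BCL2L2 with 0.15, while BAX fell by 0.27. TGF-beta and BMP targets (0.788) held SKIL with 0.41, ID1 with -0.33 and SMAD6 with -0.255. Microtubule-associated proteins (0.392, 4 rose and 2 fell) held KIF5B with 0.17, KATNA1 with 0.16, CKAP5 with 0.19 and TBCA with 0.074. Genes of SRF and YAP (0.316, 3 rose) held TAGLN with 0.26 and TPM1 with 0.17, those of paclitaxel transport and metabolism (0.452, 2 rose) CYP3A4 with 0.15, and NRF2 targets (0.687, 2 fell) PIR with -0.24. CYP3A4 was read by a probe set ending in _x_at, which can match several transcripts. Its other sets, at levels of 3.99 to 4.21, had 0.089, 0.010 and 0.017. Hypoxia and glycolysis genes (0.221, 6 fell) held EGLN3 with -0.15, nucleolar genes (0.104, 3 rose) NOP16 with 0.21, ribosomal proteins (0.0778, 6 rose) RPS19 with 0.051, and interferon-stimulated genes (0.525, 1 rose and 1 fell) IFI27 with 0.12 and USP18 with -0.12. The added names are DNAJB9 (-0.23) and PHGDH (-0.19) in the ATF4 list, HSP90AA1 (0.032) and DNAJB1 (-0.20) in the heat shock list, and BUB3 (-0.17) and ZW10 (-0.094) in the spindle checkpoint list. In the BCL2 family they are BCL2L11 (0.13), BIK (0.11) and BCL2 (-0.145), and among microtubule-associated proteins MAPRE3 (-0.13) and TBCD (-0.16).

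Adjusted over the list alone at 100 nM and 24 h, the numbers that rose and fell were 6 and 3 for ATF4, 5 and 1 for heat shock, 7 and 3 for the spindle checkpoint, 5 and 4 for BCL2, 1 and 3 for TGF-beta, 4 and 2 for microtubule-associated proteins, 3 and 0 for SRF and YAP, 2 and 0 for transport, 0 and 2 for NRF2, 0 and 6 for hypoxia, 4 and 1 for nucleolar genes, 7 and 0 for ribosomal proteins and 1 and 0 for interferon. The marker lists of melanocyte, haematopoietic, epithelial, mesenchymal, intestinal and glial genes all had a camera adjusted p of 0.975 at this dose and time. In all 6 dose comparisons the lowest camera adjusted p of a marker list was 0.259, and the sign-flip permutation test passed only for intestinal markers at 10 nM and 24 h (mean 0.044, adjusted p = 0.0093). CDC20, BUB1, BUB1B and TTK are in both the G2/M and the spindle checkpoint list, BAX is in the BCL2 and p53 lists, ATF3 in the immediate early and ATF4 lists, and SLC7A11 in the ATF4 and NRF2 lists. Mean, median and test direction differed in sign only for lists that did not pass, such as NRF2 targets here (mean 0.0023, median -0.019).

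**Figure D3:**
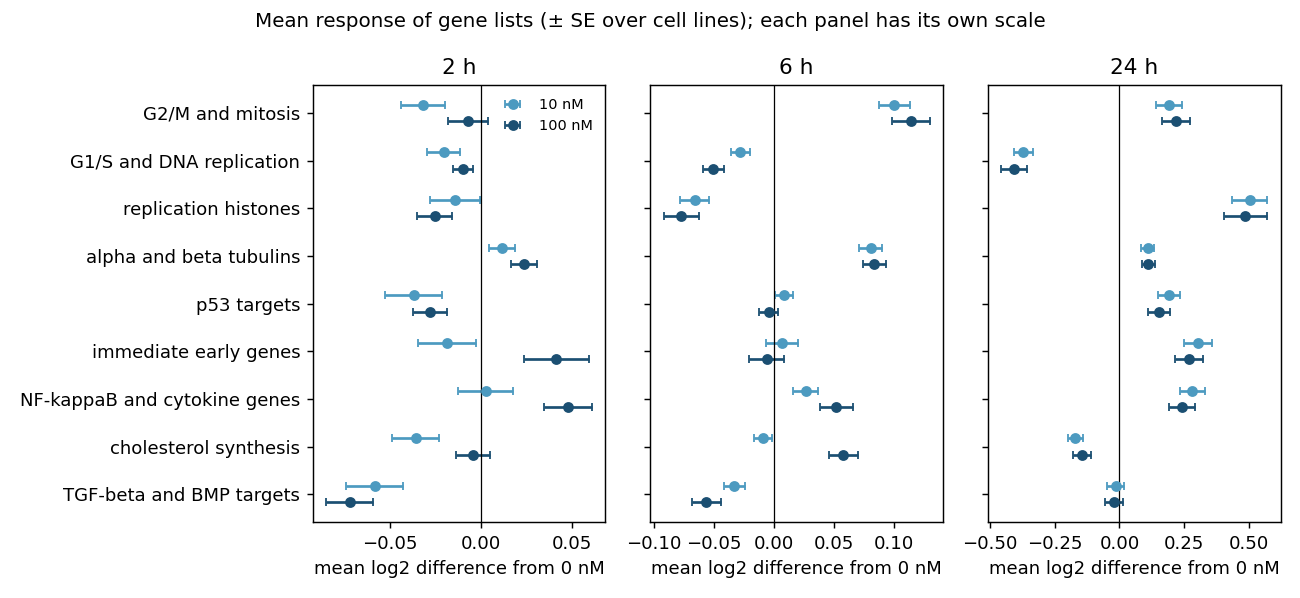
Points give the mean log2 difference from 0 nM of 9 gene lists with SE over lines, at 10 and 100 nM, with 1 panel and its own scale for each time (2, 6 and 24 h). Replication histones had a mean of -0.077 at 100 nM and 6 h and of 0.49 at 24 h.

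At 10 nM and 24 h the question was whether a dose 10 times lower changes the same genes. CXCL8 rose by 1.19 ± 0.17 (53 of 60 lines), ATF3 by 1.16 ± 0.12 (54 of 60), H2BC21 by 1.06 ± 0.13, H2BC5 by 1.04 ± 0.13, GTF2H2B by 0.98 ± 0.08 (57 of 60) and the microtubule crosslinking gene MTCL2 by 0.75 ± 0.09 (54 of 60). FBXO5 fell by 1.00 ± 0.10 (lower in 57 of 60). CCNE2 had a difference of -0.96 ± 0.11, RBL1 -0.94 ± 0.09, TOPBP1 -0.85 ± 0.09 (58 of 60), CDK1 -0.84 ± 0.11 and the uracil glycosylase gene UNG -0.68 ± 0.06. CDKN1A rose by 0.46 ± 0.08 (44 of 60, adjusted p = 4.96e-06) and TUBB3 by 0.18 ± 0.03 (46 of 60), while ABCB1 (0.093, adjusted p = 0.0551) and MAPT (-0.061, adjusted p = 0.182) did not pass. In limma 3672 genes changed, 1643 higher and 2029 lower (1884 and 1841 after quantile normalization, 1912 and 1783 after median centring), and 72 by at least 0.5 (35 higher, 37 lower).

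The lists past camera at 10 nM and 24 h were the same 9 as at 100 nM, with heat shock proteins as the tenth. G1/S genes fell in 31 of 33 members (mean -0.37, higher in 6 of 60 lines, camera adjusted p = 1.95e-30), and this was the call that held with an estimated correlation (adjusted p = 0.030). G2/M genes rose in 28 and fell in 5 members (mean 0.19, 42 of 60 lines, adjusted p = 1.04e-11; adjusted p = 0.271 with an estimated correlation), with CCNB1 up by 0.455. TOP2A (-0.315), NUSAP1 (-0.30) and CDC25C (-0.24), added names, fell with CDK1 and UBE2C. Histones rose in 11 members (mean 0.50, 52 of 60 lines, adjusted p = 2.43e-07; 0.117 with an estimated correlation). NF-kappaB genes rose in 15 members (mean 0.28, adjusted p = 1.11e-06; 0.239 with an estimated correlation), with CXCL2 up by 0.60 and TNFAIP3 by 0.44. Immediate early genes rose in 12 and fell in 2 (mean 0.30, adjusted p = 4.07e-06; 0.239 with an estimated correlation), with KLF4 up by 0.52, while JUND (-0.55) and MYC (-0.15), added names, fell. Cholesterol synthesis genes fell in 8 of 10 members (mean -0.17, adjusted p = 0.000101; 0.239 with an estimated correlation), with INSIG1 down by 0.37 and DHCR7 by 0.29. Targets of p53 rose in 11 members (mean 0.19, adjusted p = 7.92e-05; 0.271 with an estimated correlation). Tubulins rose in 6 members (mean 0.11, adjusted p = 0.0157; 0.344 with an estimated correlation). The gamma, delta and epsilon list fell in 4 members and rose in TUBD1, an added name (adjusted p = 0.0249; 0.239 with an estimated correlation). Heat shock proteins rose in 4 and fell in DNAJB1, an added name (adjusted p = 0.0157; 0.271 with an estimated correlation). Adjusted over the list alone, the numbers that rose and fell were 1 and 31 for G1/S, 30 and 6 for G2/M, 11 and 1 for histones, 17 and 1 for NF-kappaB, 15 and 3 for immediate early genes, 0 and 8 for cholesterol synthesis, 11 and 0 for p53, 6 and 2 for tubulins, 1 and 4 for the gamma list and 4 and 1 for heat shock.

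The responses to the 2 doses were compared at 24 h. ATF3, CXCL8 and the H2B genes rose at both, FBXO5, CCNE2 and CDK1 fell at both, and among genes past the test at both doses 1349 were higher, 1664 were lower and 0 went opposite ways, out of the 3672 and 3830 genes past it at 10 and 100 nM. Across genes, which are not independent replicates, the Pearson correlation of the mean differences was 0.961. Shared control arrays contribute to that value. In 1000 simulated sets the mean response of each gene was removed and each line's differences got a random sign, the same for both doses. There the median r was 0.636 and the highest 0.807. These sets keep the shared controls but also any response of a single line common to both doses. They do not measure the controls alone. The covariance was 0.0136 against a simulated median of 0.000799, a difference of 0.0128. With the lines split into random sets of equal size so that no control was shared, the median r was 0.839 (0.716 to 0.874 over 100 splits), and 0.842 for sets of the same dose.

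At 6 h the question was which changes come first. At 100 nM, 29 of 36 G2/M members and 7 of 13 tubulins rose, while 11 of 33 G1/S members and 4 of 13 histones fell, the histones opposite to 24 h. Among G2/M genes, CKS2 rose by 0.165 ± 0.02 (55 of 60 lines, adjusted p = 1.07e-11), TTK by 0.19 (53 of 60), TPX2 by 0.17 (52 of 60) and the cyclin gene CCNB1 by 0.14 (52 of 60). TUBB3 rose by 0.15 ± 0.02 (51 of 60, adjusted p = 1.5e-08), TUBB2A by 0.18 (53 of 60), TUBB4B by 0.098 and TUBB by 0.075. CCNE1 had a difference of -0.20, MCM3 -0.098, H2AC6 -0.22 and H2BC12 -0.10. The genes that rose the most were TRAPPC10 by 0.38 ± 0.05 (51 of 60), CXCL8 by 0.36 ± 0.06 (46 of 60), GTF2H2B by 0.36 ± 0.05, the bornavirus-derived gene EBLN2 by 0.35 ± 0.05 and MTCL2 by 0.28 ± 0.04. The glycolipid anchor gene PIGL fell by 0.37 ± 0.04 (lower in 52 of 60), TAF1D by 0.29, CTC-338M12.4 by 0.27, TSPYL4 by 0.25 and RSRP1 by 0.21. CDKN1A (0.095, adjusted p = 0.0769), ABCB1 (adjusted p = 0.477) and MAPT (adjusted p = 0.901) did not pass. In limma 234 genes were higher and 328 lower at 100 nM, and 250 changed at 10 nM (133 higher, 117 lower, or 128 and 145 after median centring), with 0 of them by 0.5 or more at either dose. With all groups in one fit, 14 were higher and 18 lower at 100 nM and 7 and 1 at 10 nM. An unadjusted p under 0.05 was reached by 1951 and 1473 genes. At 10 nM and 6 h TRAPPC10 rose by 0.40 (49 of 60), GTF2H2B by 0.36, MTCL2 by 0.29, EBLN2 by 0.28, DBF4B by 0.23 and CXCL8 by 0.25 (42 of 60). PIGL fell by 0.29, RSRP1 and CCNE1 by 0.17 and MYC by 0.16. CDKN1A (adjusted p = 0.452), ABCB1 (0.795) and MAPT (0.784) did not pass there, while TUBB3 rose by 0.125 (46 of 60).

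At 100 nM and 6 h, 12 lists passed camera. G2/M genes rose in 29 members (mean 0.11, higher in 53 of 60 lines, adjusted p = 1.4e-54; adjusted p = 0.000246 with an estimated correlation) and tubulins in 7 of 13 (mean 0.084, 54 of 60 lines, 2.34e-14; 2.42e-05 with an estimated correlation). G1/S genes fell in 11 members (mean -0.050, adjusted p = 1.48e-09) and histones in 4 (mean -0.077, 1.1e-05). Falls were also seen in nucleolar and ribosome biogenesis genes in 3 of 8 (mean -0.041, 7.3e-05) with NOLC1 and RRS1 down by 0.10, and TGF-beta and BMP targets in 3 of 10 (mean -0.056, 0.00628) with SMAD7 down by 0.20 and ID2 by 0.11. Cholesterol synthesis genes rose in 3 of 10 members (mean 0.058, 46 of 60 lines, adjusted p = 0.000116) with the sterol sensor gene INSIG1 up by 0.26 (51 of 60) and HMGCS1 by 0.13, opposite to their fall at 24 h. NF-kappaB genes rose in 2 (mean 0.052, adjusted p = 0.000513) and ATF4 and unfolded protein response genes in 4 (0.000513), with the cystine transporter gene SLC7A11 up by 0.17 and HERPUD1 by 0.086. NRF2 targets rose in 2 (0.0026) with TXNRD1 up by 0.079, and spindle checkpoint genes in 3 (0.000513) with BUB1 up by 0.13 and BUB1B by 0.11. With an estimated correlation these 9 lists kept adjusted p values from 0.0019 to 0.0369. Microtubule-associated proteins (1 rose, CKAP5 by 0.092, adjusted p = 0.0282) did not hold, with adjusted p = 0.0632 with an estimated correlation. Adjusted over the list alone, the numbers that rose and fell were 31 and 0 for G2/M, 10 and 0 for tubulins, 1 and 16 for G1/S, 0 and 5 for histones, 0 and 4 for nucleolar genes, 0 and 5 for TGF-beta, 5 and 0 for cholesterol synthesis, 4 and 0 for NF-kappaB, 5 and 1 for ATF4, 2 and 0 for NRF2, 8 and 1 for the spindle checkpoint and 1 and 0 for microtubule-associated proteins. The other 10 pathway lists did not pass camera there.

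At 10 nM and 6 h, 8 lists passed camera. G2/M genes rose in 27 members (mean 0.10, 51 of 60 lines, adjusted p = 6e-63; 6.72e-06 with an estimated correlation), with the spindle pole gene ASPM up by 0.16 (52 of 60) and the topoisomerase gene TOP2A and the kinesin gene KIF2C by 0.14. Tubulins rose in 7 (55 of 60 lines, adjusted p = 3.6e-17; 2.67e-06 with an estimated correlation), with TUBB2A up by 0.195 and TUBA1A by 0.13. Histones fell in 3 (mean -0.066, adjusted p = 0.000144; 0.00638 with an estimated correlation) and nucleolar genes in 2 (mean -0.034, 0.000318; 0.000764 with an estimated correlation). G1/S genes fell in 7 and rose in ORC6, an added name (mean -0.028, adjusted p = 0.000506; 0.0917 with an estimated correlation) and spindle checkpoint genes rose in 3 and fell in 1 (0.00226; 0.0779 with an estimated correlation). NF-kappaB genes, of which CXCL8 rose (0.0373; 0.0969 with an estimated correlation), and microtubule-associated proteins with 0 members past the test (0.0154; 0.0779 with an estimated correlation) did not hold. Adjusted over the list alone, the numbers that rose and fell were 32 and 0 for G2/M, 9 and 0 for tubulins, 0 and 6 for histones, 0 and 3 for nucleolar genes, 2 and 10 for G1/S, 5 and 2 for the spindle checkpoint, 1 and 0 for NF-kappaB and 3 and 0 for microtubule-associated proteins.

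At 2 h the changes were small. At 100 nM the transcription factor genes JUN, ATF3 and KLF6 rose by 0.43 ± 0.06 (45 of 60 lines, adjusted p = 2.67e-06), 0.33 ± 0.05 (46 of 60) and 0.22 ± 0.04, CXCL8 rose by 0.31 ± 0.05 (48 of 60) and STAP1 by 0.16 ± 0.03. TAF15 fell by 0.24 ± 0.04, the lamin gene LMNB1 by 0.21 ± 0.03 (lower in 50 of 60), and the BMP and Notch targets ID1, HES1 and ID2 by 0.18 ± 0.02 (49 of 60), 0.185 ± 0.04 and 0.14 ± 0.03. TUBB3 rose by 0.065 ± 0.02 (38 of 60, adjusted p = 0.0278), and ABCB1 (adjusted p = 0.957), MAPT (0.731) and CDKN1A (0.358) did not pass. TGF-beta and BMP targets fell in 4 of 10 members, or 5 adjusted over the list alone, with SMAD7 (-0.16) and ID3 (-0.10) as added names (mean -0.072, higher in 11 of 60 lines, camera adjusted p = 0.000191; 0.0159 with an estimated correlation). Tubulins rose in TUBB3 and TUBB4B, the latter an added name, also adjusted over the list alone (adjusted p = 0.0151; 0.117 with an estimated correlation), and NF-kappaB genes in 1, also adjusted over the list alone (0.00177; 0.117 with an estimated correlation). In limma 241 genes changed (113 higher, 128 lower; 192 and 80 after median centring), 476 without the line LOX and 52 with all groups in one fit.

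At 10 nM and 2 h, 123 genes passed limma (25 higher, 98 lower; 21 and 38 after quantile normalization, 44 and 77 after median centring). The count was 37 with all groups in one fit and fell to 67 without DU-145, 71 without SR, 80 without MOLT-4 and 81 without IGR-OV1. The follistatin-like gene FSTL3 rose by 0.18 ± 0.04 (46 of 59 lines) and the ephrin gene EFNA2 by 0.135 ± 0.03, and SPATA1 and IFNA8 also met the naming rule. The mean levels of EFNA2, SPATA1 and IFNA8 (3.80, 3.52 and 3.47) lay under the lower quartile of every array (3.93 to 4.24), so their signal is not shown to be above background. The zinc transporter gene SLC30A1 fell by 0.175 ± 0.02 (lower in 51 of 59, adjusted p = 1.43e-06), the zinc finger gene ZNF264 by 0.22 ± 0.04, the splicing kinase gene CLK4 by 0.21 ± 0.04, CSRNP2 by 0.18 ± 0.04 and BRF2 by 0.165 ± 0.04. TUBB3 (adjusted p = 0.0647), ABCB1 (0.889), MAPT (0.55) and CDKN1A (0.888) did not pass. No list call held at this dose with an estimated correlation. TGF-beta and BMP targets fell in ID1 (-0.16), ID2 (-0.145) and ID3 (-0.16) (mean -0.059, camera adjusted p = 0.0207; 0.30 with an estimated correlation). G2/M genes fell in CENPA and HMMR (0.0207; 0.534 with an estimated correlation) and the spindle checkpoint list in MAD2L1BP (0.0416; 0.387 with an estimated correlation). Tubulins, with 0 members past the test (0.0306), and SRF and YAP targets with CCN2 higher by 0.155 (0.0416) had 0.30 with an estimated correlation. The list members in this paragraph are added names. Adjusted over the list alone, the numbers that rose and fell were 0 and 5 for TGF-beta, 0 and 3 for G2/M, 0 and 4 for the spindle checkpoint, 1 and 0 for tubulins and 2 and 0 for SRF and YAP. At both doses 0 genes changed by 0.5 or more at 2 h, while 2170 genes at 10 nM and 2184 at 100 nM had an unadjusted p under 0.05.

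The comparison of 100 with 10 nM asked whether dose matters above 10 nM. At 6 h INSIG1 was higher at 100 nM by 0.21 ± 0.03 (49 of 60 lines, adjusted p = 1.18e-06), HMGCS1 by 0.12 ± 0.02, MSMO1 by 0.11 ± 0.02 and IDI1 by 0.10 ± 0.02, with the chaperone gene CHORDC1 by 0.11 ± 0.02. ASTE1 (-0.14), PDZRN4 (-0.11, at a mean level of 3.64, under the lower quartile of every array), CLK2 (-0.097) and CIRBP (-0.071) were lower, so that 9 genes differed in limma, and 0 with all groups in one fit. Lists were not tested in this comparison. At 2 h CXCL8, also not called with all groups in one fit, was higher by 0.21 ± 0.04 (46 of 59, adjusted p = 0.0138). At 24 h CRIP2 had a difference of -0.24 ± 0.04 (lower in 50 of 59, adjusted p = 0.000144). Each was the 1 gene called in limma at its time. Unadjusted p values under 0.05 were reached by 1151, 812 and 848 genes at 2, 6 and 24 h. The count at 2 h was 2 without MOLT-4, SK-MEL-28, SK-OV-3, SR or T-47D, and the count at 24 h was 3 without HCC-2998 or MALME-3M and 2 without DU-145, HCT-116, MDA-MB-468, NCI-H322M, OVCAR-8, SNB-19 or the renal line that is first by name.

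The time comparisons tested whether the response itself differed between times. From 6 to 24 h at 100 nM, EGR1 turned from -0.09 to 1.09 (difference 1.18), H2BC21 from -0.17 to 0.98 (1.15) and H2BC5 gained 1.16. CDK1 went from 0.00 to -0.98 (-0.99), FBXO5 changed by -1.14, RBL1 by -1.01, CCNE2 by -0.94 and TOPBP1 by -0.92. At 10 nM, H2BC21 gained 1.19, H2BC5 1.16, ATF3 1.05 and H2AC6 1.01, and RBL1 changed by -0.98. The response differed in 2718 genes at 100 nM (1307 higher, 1411 lower, 67 by at least 0.5) and in 2669 at 10 nM (1239 higher, 1430 lower, 57 by at least 0.5). After quantile normalization the larger side turned to higher at both doses (1519 and 1215 at 100 nM, 1441 and 1260 at 10 nM). From 2 to 6 h at 100 nM, JUN returned from 0.43 to 0.06 (-0.37) and ATF3 from 0.33 to 0.06 (-0.28), while TRAPPC10 gained 0.33, and 376 genes differed (192 higher, 184 lower; 171 and 179 after quantile normalization, 128 and 274 after median centring). At 10 nM, the chromosomal passenger gene INCENP gained 0.33, TRAPPC10 0.32, ZNF264 0.31 and the mitotic kinesin gene KIF18A 0.29. The matrix gene CCN2 changed by -0.22, and 270 genes differed (230 higher, 40 lower; 120 and 75 after quantile normalization).

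Culture time alone, from 2 to 24 h at 0 nM, is the background of these comparisons. The stress regulator gene DDIT4 rose by 1.08 (54 of 60 lines), FAM200C by 1.01 (60 of 60), ZNF322 by 0.80 and KMT5B by 0.75, whereas MAFF fell by 1.17 (lower in 53 of 60), CCN2 by 1.09 (52 of 60), SMAD7 by 1.01 and ATF3 and KLF11 by 0.97. In limma 5347 genes changed (2794 higher, 2553 lower, 65 by at least 0.5). Controls of the same time were used for every response above.

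Tissue of origin was compared because the panel spans several tumour types. At 10 nM and 24 h the zinc finger gene ZNF721 had a mean response of 1.32 ± 0.48 (SD, n = 6) in leukemia lines and 0.25 to 0.48 in the other tissues (limma F test, adjusted p = 0.000186). The matrix gene CCN1 was higher in 9 of 9 melanoma lines (mean 1.24 ± 0.70, SD) and was lower in all 6 CNS lines (mean -0.43). The chemokine receptor gene ACKR3 was lower in CNS lines (-1.28 ± 1.03, SD), the kinase gene PLK2 was lower in CNS (-0.82) and higher in melanoma lines (0.57), and FCGR2A was lower in melanoma lines (-0.63). DBT, SLC35E1 and DIP2A were highest in leukemia lines (0.88, 1.15 and 1.14), CCT5 was lowest there (-0.19) and ST8SIA1 in melanoma lines (-0.47). ZNF721, DBT, SLC35E1 and DIP2A were read by probe sets ending in _x_at, which can match several transcripts. Among the leukemia arrays at 10 nM and 24 h, those of HL-60 and MOLT-4 were among the 25 of low quality. At 100 nM, FCGR2A was lower in 9 of 9 melanoma lines (-0.73 ± 0.38, SD, adjusted p = 0.000289 by limma), GAL3ST1 in 8 of 8 renal lines (-0.84 ± 0.50, SD), and the polyamine gene SRM differed between colon (-1.54) and CNS lines (0.205). The mean level of ST8SIA1 over all arrays lay within the range of array lower quartiles (3.93 to 4.24). FCGR2A (4.25) and GAL3ST1 (4.55) lay little above it. A tissue with little signal of a gene can hardly show a fall of it. The tissue differences of these genes are therefore not shown to be different responses to the drug. Their levels were not compared between tissues. The response differed between tissues in 122 genes at 10 nM (58 lines, 8 tissues) and 32 genes at 100 nM (52 lines, 7 tissues, without leukemia, which had 5 lines there), and 0 genes passed a rank test at either dose.

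Single lines moved these tissue counts. At 10 nM, 25 genes passed without any 1 of the CNS lines (SF-268, SF-295, SF-539, SNB-19, SNB-75, U251) and 27 without any 1 of the leukemia lines (CCRF-CEM, HL-60, K-562, MOLT-4, RPMI-8226, SR), because that tissue then had fewer than 6 lines and left the test. At 100 nM the count of 32 rose to 54 without CAKI-1. It was 21 without A498 or the renal line that is first by name, 20 without KM12, 18 without ACHN, COLO-205, HT29, NCI-H460 or OVCAR-4, 17 without HCT-116 or LOX, 16 without NCI-ADR-RES or UO-31 and 15 without MALME-3M or TK-10. It was 14 without A549, M14, NCI-H226, NCI-H23, NCI-H322M, UACC-257 or UACC-62, 13 without SK-MEL-2 or SK-MEL-28 and 11 without SK-MEL-5. Among gene lists at 10 nM, permutation of the tissue labels gave adjusted p = 0.0216 for the spindle checkpoint (CNS mean 0.28, breast 0.25, leukemia -0.08), 0.0430 for SRF and YAP targets (melanoma 0.24, CNS -0.13) and 0.0430 for interferon-stimulated genes (CNS -0.35). At 100 nM the lowest adjusted permutation p of a list was 0.182. The size of a line's response, the root mean square of its gene differences, differed between tissues with permutation p = 0.209 at 10 nM and 0.0271 at 100 nM.

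Leukemia lines, which grow in suspension, were compared with the other lines at 100 nM and 24 h. The desaturase gene SCD5 had a mean response of 1.24 ± 0.83 (SD, n = 5) in leukemia lines and 0.10 in the others (difference 1.14), and ZNF721 of 1.01 ± 0.45 (SD) and 0.36. BEX4 had -1.49 ± 1.64 (SD) in leukemia lines (difference -1.41), KLF10 -0.45 ± 0.59 (SD) against 0.51 in the others, and the activation marker gene CD69, with -0.94 ± 1.17 (SD) in leukemia lines, differed by -0.92. The mean level of CD69 over all arrays (3.67) lay under the lower quartile of every array (3.93 to 4.24). ZNF721 was read by the same _x_at probe set as above. In limma 44 genes differed (18 higher, 26 lower, 23 by at least 0.5) between 5 and 54 lines, 15 were higher and 56 lower after median centring, and 0 passed a rank test. The count was 8 without CCRF-CEM, 17 without MOLT-4, 72 without RPMI-8226, 74 without HS-578T, 77 without SW-620 and 78 without K-562.

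The response at 24 h differed in size between lines, and baseline levels of ABCB1, TUBB3, MAPT and the G2/M list, from the 0 nM array at 2 h, were compared with it. The root mean square was 0.285 ± 0.069 (SD, n = 60) at 10 nM, from 0.166 in UO-31 to 0.449 in HT29, and 0.309 ± 0.068 (SD, n = 59) at 100 nM, from 0.204 in NCI-ADR-RES to 0.525 in HS-578T. At 2 h it was 0.225 and 0.215, and at 6 h 0.204 and 0.211, times at which far fewer genes passed limma. The measure may therefore hold variation between arrays as well as response. The array of HS-578T at 100 nM and 24 h was among those of low quality, and the relations were not recomputed without such arrays. Higher ABCB1 went with a smaller response at 10 nM (r = -0.368, permutation p = 0.00375, adjusted p = 0.0300; without the 2 farthest lines r = -0.261, permutation p = 0.0439; tissue means removed r = -0.385) but not by rank (rho = -0.180, permutation p = 0.169, adjusted p = 0.246). With response size as the number of genes that differ by at least 1, it did not pass after adjustment (r = -0.291, permutation p = 0.0230, adjusted p = 0.0613; rho = -0.172, adjusted p = 0.373). At 100 nM r was -0.178 (permutation p = 0.174, adjusted p = 0.254) and rho -0.0759 (permutation p = 0.567, adjusted p = 0.698). The difference between the doses was not tested. The relation rests on 5 lines with ABCB1 above a level of 6 (NCI-ADR-RES 11.43, HCT-15 10.42, CAKI-1 8.43, UO-31 8.04 and ACHN 6.01), since among the other 55 lines r was -0.119 (permutation p = 0.388) at 10 nM, a division chosen after the values were seen.

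**Figure D4:**
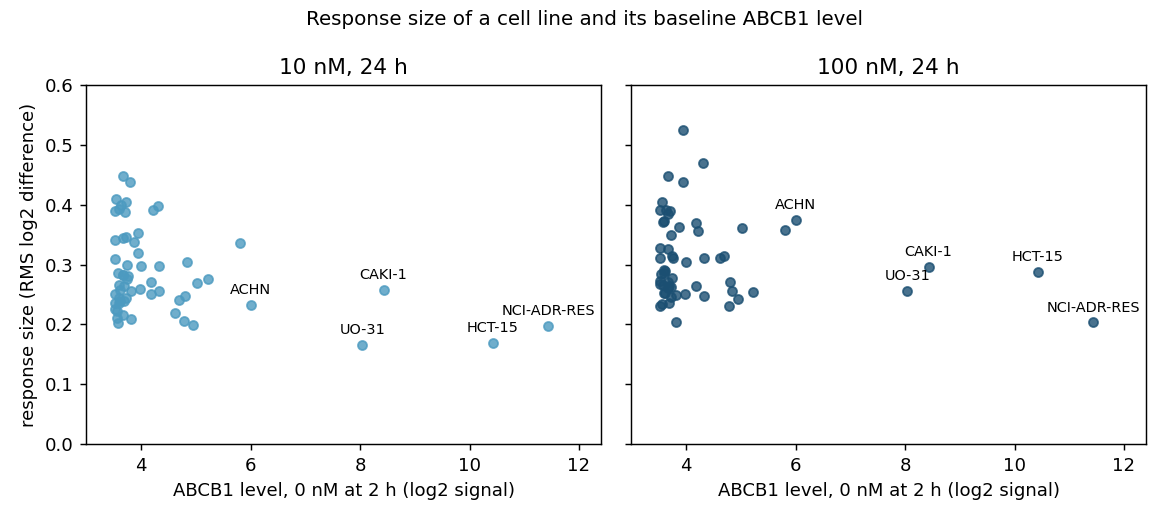
Each point is a cell line, with its ABCB1 level at 0 nM and 2 h (log2 signal) and the root mean square of its log2 differences at 24 h, for 10 nM (left) and 100 nM (right). The 5 lines with the highest ABCB1 are named, and HCT-15 moved from rank 2 of 60 at 10 nM to rank 29 of 59 at 100 nM.

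Baseline G2/M expression went with a larger response at 100 nM (r = 0.452, permutation p = 0.00045, adjusted p = 0.0072; rho = 0.519, permutation p = 3e-05, adjusted p = 0.00048; r = 0.429 without the 2 farthest lines and 0.363 with tissue means removed). At 10 nM it did not pass after adjustment (r = 0.263, permutation p = 0.0414, adjusted p = 0.0829; rho = 0.258, permutation p = 0.0479, adjusted p = 0.110). The G2/M response and ABCB1 were related by rank (10 nM rho = -0.479, permutation p = 0.00016, adjusted p = 0.00128; 100 nM rho = -0.449, permutation p = 0.00055, adjusted p = 0.00293). By Pearson correlation it did not pass (r = -0.289 and -0.323, permutation p = 0.0237 and 0.0129, adjusted p = 0.0803 and 0.0687; -0.375 and -0.388 without the 2 farthest lines; -0.194 and -0.231 with tissue means removed). The median ABCB1 level of 3.74 lay under the lower quartile of every array (3.93 to 4.24), so these ranks order most lines by a signal not shown to be above background. TUBB3 and the G2/M response had rho = -0.370 (permutation p = 0.004, adjusted p = 0.016) and r = -0.287 (permutation p = 0.0255, adjusted p = 0.0803; -0.462 without the 2 farthest lines) at 10 nM, and rho = -0.306 (permutation p = 0.0188, adjusted p = 0.0603) and r = -0.280 (permutation p = 0.0320, adjusted p = 0.0803) at 100 nM. MAPT had no relation past the test, with the lowest adjusted p at 0.246 for rho and 0.254 for r. The family held 16 relations, and the TUBB3 level carries the limit of its probe set given above.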

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

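Tests chosen only after the result was seen were that of other probe sets of the fallen G2/M members, the division of lines by ABCB1 level and, for histones, the condition on list members at plain probe sets.

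The mean of the replication histone list rose at 24 h, although not every histone probe set did. The technical candidates tested were probe sets that bind several histone transcripts and differences in RNA quality. Other technical causes were not tested. The median response at 100 nM of the 41 histone probe sets whose names end in a plain _at was 0.0447 (from -1.04 to 1.19, 28 above 0), against 0.61 for 8 _s_at and 0.67 for 14 _x_at sets, which met the written criterion for cross-hybridisation (under 0.1). It stays open because 36 of the 41 plain sets lie at a level under 5. The 4 list members on plain sets that rose had a median of 0.51, a condition added after the value was seen. They were chosen because they rose, so this median cannot decide the question. The tables argue against RNA degradation or labelling differences between arrays as the whole cause, as far as the covariates measure them. The list mean of 0.487 was 0.470 with quality covariates (95% interval 0.291 to 0.650), and its r with the beta-actin difference was 0.0869 (permutation p = 0.514). How far the labelling kit, the same for all arrays, captures each histone transcript was not tested. A biological candidate, loss of S-phase transcripts in the same lines, also stays open, with r = -0.280 to the G1/S mean at 100 nM (permutation p = 0.0315, adjusted p = 0.0420; rho = -0.159; r = -0.150 without the 2 farthest lines) and -0.176 at 10 nM (permutation p = 0.178).

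CDK1, UBE2C, TOP2A, NUSAP1 and CDC25C fell at 24 h while most G2/M members rose. The tables argue against a probe set that measures another transcript, since other probe sets of these genes had a median of -0.710 (CDK1 -1.06 and -1.05, TOP2A -1.10, NUSAP1 -0.37, CDC25C -0.15 and 0.02), and UBE2C has 1 set. The candidate explanation that they follow the G1/S genes had r = 0.489 with the G1/S mean at 100 nM (adjusted p = 0.00048) against 0.138 with the remaining G2/M members, and 0.376 against 0.314 at 10 nM. By rank the values were 0.329 against 0.315 and 0.316 against 0.390, so this holds for r alone, and without the 2 farthest lines r was 0.333 against 0.216 and 0.287 against 0.265, differences that were not tested. All of these means share the control array of each line.

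The response was smaller at 10 nM in lines with high baseline ABCB1, for which efflux of paclitaxel is a candidate explanation (r = -0.368 at 10 nM and -0.178 at 100 nM; -0.291 at 10 nM, adjusted p = 0.0613, with size as a number of genes). The 5 lines with a level above 6 had a mean size of 0.204 ± 0.040 (SD) at 10 nM against 0.292 ± 0.067 in the others, and all 5 lay under the median of the others. UO-31, HCT-15 and NCI-ADR-RES held ranks 1, 2 and 3 of 60 from the smallest, ACHN rank 13 and CAKI-1 rank 26. The next line by level, A498 at 5.81, fell outside this division and had a size of 0.336 (rank 45 of 60). At 100 nM the means were 0.283 and 0.311, with 3 of 5 under that median. Among the others r was -0.119 at 10 nM (n = 55, permutation p = 0.388) and -0.0257 at 100 nM (n = 54, permutation p = 0.854). Removing tissue means left r at -0.385, and no other property of these 5 lines was tested.

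The response differed between times by a test of the difference in 270 genes (6 against 2 h, 10 nM), 376 (6 against 2 h, 100 nM), 2669 (24 against 6 h, 10 nM) and 2718 (24 against 6 h, 100 nM). It differed between tissues in 122 genes at 10 nM and 32 at 100 nM, and between leukemia and other lines in 44. The list means that differed between tissues at 10 nM were interferon-stimulated genes (adjusted p = 0.0430), SRF and YAP targets (0.0430) and the spindle checkpoint (0.0216).

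Of 64 groups of lines of a tissue, 6 held a line far from the others, where chance gives about 1 in 20 groups. At 10 nM these were HCC-2998 among colon lines for SRF and YAP targets (0.37, nearest 0.051) and RXF-393 among renal lines for interferon-stimulated genes (-0.52, nearest -0.081), whose array was among the 25 of low quality. At 100 nM the response size was 0.525 in the breast line HS-578T (nearest 0.328), whose array was also among the 25 of low quality, and 0.254 in the CNS line SF-295 (nearest 0.363). Interferon-stimulated genes were at 0.38 in the melanoma line UACC-257 (nearest 0.12) and -0.50 in the ovarian line OVCAR-5 (nearest -0.17) at 100 nM. Among 3151 probe sets with no or several genes, which the tests by gene left out, 890 passed limma at 100 nM and 24 h (511 higher, 379 lower, 27 by at least 0.5).

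Of 100 splits of the samples, the real one included, 1 gave as many genes as the real split (the real one itself) in each comparison named here. That share, 1 of 100, is the lowest these splits can give, for each comparison taken alone. The highest count of another split was 0 at 2 h at both doses (real 123 and 241), 1 and 2 at 6 h (10 and 100 nM, 250 for 10 nM) and 179 and 650 at 24 h (3672 and 3830). It was 0 for 100 against 10 nM at 6 h (real 9), 0 and 1 for 6 against 2 h (270 and 376), 27 and 298 for 24 against 6 h (2669 and 2718) and 413 for culture time (5347). It was 33 and 1 between tissues (122 and 32) and 31 for leukemia lines (44). With single lines left out, the leukemia count ran from 8 (CCRF-CEM) to 78 (K-562). Tissue and leukemia genes did not pass a rank test, so chance is not excluded for the tissue and leukemia counts. For 100 against 10 nM at 2 and 24 h, 3 of 100 splits gave at least the 1 gene of the real split (highest other 4 and 1). Since another split gave more genes than the real one at 2 h and as many at 24 h, these counts of 1 gene do not exclude chance.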

How the results depend on the processing

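Alternatives chosen after the data were seen were the fits without low-quality arrays and with array quality covariates. Of 484 counts and relations under alternatives, 365 stayed within 1.5 times or on their side of the threshold, 4 were weaker, 115 moved and 0 reversed. Of 865 list results 691 kept their side and 174 were weaker, and of 4833 named-gene results 4331 kept it, 480 were weaker, 11 stronger, 11 moved, with 0 reversed in both. No scaling turned the direction of a list past camera or moved the median of all genes by over 0.1. Of 379 named-gene results, 86 kept their side under every alternative run and 255 under every one but no replicate block. Values follow with the reported value in brackets. The cause was not tested unless given.

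Without the replicate block, counts were 0 [123] and 1 [241] at 2 h (10 and 100 nM), 2 [250] and 2 at 6 h, 121 [3672] and 166 [3830] at 24 h, 0 for 100 against 10 nM at each time [1, 9, 1], 0 [270] and 0 [376] for 6 against 2 h, 8 [2669] and 10 [2718] for 24 against 6 h, 389 [5347] for culture time, and 0 for tissues [122, 32] and leukemia [44], because differences between lines then enter the error. Differences of at least 0.5 were 42 [72] at 10 nM and 24 h, 6 [57] and 9 [67] for 24 against 6 h, 35 [65] for culture time and 0 [23] for leukemia. Lists were 0 [5] and 0 [3] at 2 h and 2 [8] and 4 [12] at 6 h.

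With all groups in one fit, counts were 37 and 52 at 2 h, 8 and 32 at 6 h, and 0 and 0 for 100 against 10 nM at 2 and 6 h. At an adjusted p under 0.01, fewer by construction, they were 20 and 36 at 2 h, 153 and 316 at 6 h, 0 for 100 against 10 nM at 2 h, 87 and 103 for 6 against 2 h, 1706 and 1657 for 24 against 6 h, 32 and 1 for tissues and 6 for leukemia, with 0 lists at 10 nM and 2 h and 0 tissue lists [3]. Without leukemia lines they were 63 and 99 at 2 h, 2 for 100 against 10 nM at 2 h, 126 for 6 against 2 h at 10 nM and 27 for tissues at 10 nM (fewer tissues), with 1 tissue list. Without lines of shared origin, tissues at 10 nM gave 31 genes and 0 lists, where CNS, without U251, had fewer than 6 lines and left the test.

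Without low-quality arrays, counts were 70 and 506 at 2 h, 142 for 6 against 2 h at 10 nM, 21 and 6 for tissues and 88 for leukemia, with 5 lists at 100 nM and 2 h. Leukemia at 10 nM and breast and CNS at 100 nM then had fewer than 6 lines and left the tissue test. The tissue counts of this fit are therefore not a measure of array quality alone. With quality covariates they were 201 at 10 nM and 2 h, 50 and 15 for tissues and 14 for leukemia (7 by at least 0.5), with 3 lists at 10 nM and 2 h. With arrayWeights they were 428 at 100 nM and 2 h, 426 at 10 nM and 6 h, 2 and 16 for 100 against 10 nM at 2 and 24 h and 101 for tissues at 100 nM, with 2 lists at 10 nM and 2 h.

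Quantile normalization gave 59 genes at 10 nM and 2 h, with 1 and 5 lists at 2 h. Median centring gave 204 and 21 for tissues, 71 for leukemia (35 by at least 0.5) and 1 tissue list. Leaving out the 33.3% of genes with the lowest means gave 106 at 100 nM and 2 h, 2 for 100 against 10 nM at 24 h, 203 for 6 against 2 h at 100 nM, 20 for tissues at 100 nM and 6 lists at 100 nM and 2 h. The mean of probe sets gave 0 for 100 against 10 nM at 2 h. The rank test gave 0 for tissues and leukemia (0 by at least 0.5), with 1 list at 10 nM and 2 h and 4 at 10 nM and 6 h. For leukemia, with 5 lines, it could hardly have passed a gene. Higher and lower genes, where a scaling moved their share by over 10 points or turned the larger side, were 21 and 38 with quantiles and 44 and 77 with medians at 10 nM and 2 h [25, 98], 192 and 80 with medians at 100 nM and 2 h [113, 128], 120 and 75 with quantiles and 153 and 87 with medians for 6 against 2 h at 10 nM [230, 40], 171 and 179 with quantiles and 128 and 274 with medians for 6 against 2 h at 100 nM [192, 184], 1519 and 1215 with quantiles and 1612 and 1157 with medians for 24 against 6 h at 100 nM [1307, 1411], 1441 and 1260 with quantiles and 1489 and 1208 with medians for it at 10 nM [1239, 1430], 128 and 145 with medians at 10 nM and 6 h [133, 117], 1884 and 1841 with quantiles and 1912 and 1783 with medians at 10 nM and 24 h [1643, 2029], 2055 and 1821 with quantiles and 2263 and 1735 with medians at 100 nM and 24 h [1806, 2024] and 15 and 56 with medians for leukemia [18, 26].

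An estimated correlation left 0 and 1 lists at 2 h, 4 at 10 nM and 6 h, 1 [10] and 0 [9] at 24 h, and sign flips gave 9 and 8 at 2 h and 16 and 15 at 24 h. Robust eBayes moved no count by over 1.5 times and turned no named gene to the other side, and it was not run for camera. Without the 2 farthest lines, r with response size was 0.220 for G2/M and -0.0387 for MAPT at 10 nM and 0.00378 for TUBB3 at 100 nM. With tissue means removed, it was 0.214 for G2/M at 10 nM and 0.0230 for TUBB3 at 100 nM, and r of ABCB1 with the G2/M response was -0.194 and -0.231. With size as the number of genes that differ by at least 1, r with ABCB1 at 10 nM was -0.291 (adjusted p = 0.0613) and its adjusted call was lost. The agreement of doses was 0.839 [0.961] with no shared controls.

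Leaving out each line in turn gave 67 (DU-145) to 165 and 162 to 476 (LOX) at 2 h, 229 to 344 and 515 to 638 at 6 h, 3563 to 3773 and 3714 to 4114 at 24 h, 1 to 2, 6 to 12 and 1 to 3 for 100 against 10 nM, 181 to 382 and 276 to 471 for 6 against 2 h, 2510 to 2727 and 2582 to 2877 for 24 against 6 h, 5202 to 5476 for culture time, 25 to 182 and 11 to 54 for tissues and 8 (CCRF-CEM) to 78 (K-562) for leukemia.

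Limits are 1 array per line, dose and time, no detection calls used here and so no known signal over background, probe sets that bind several transcripts, and a preset camera correlation that called 4.72 and 4.86 of 22 lists in unchanged data at 24 h.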

Other observations

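At 0 nM and 2 h, melanocyte markers had a mean level of 10.07 ± 2.33 (SD) in melanoma lines and 4.13 to 4.68 in the other tissues, and haematopoietic markers 8.87 ± 1.14 in leukemia lines and 4.27 to 4.92 elsewhere. Epithelial markers were highest in colon lines (10.16 ± 0.87) and mesenchymal markers in CNS lines (9.61 ± 1.29). Intestinal markers reached 6.66 ± 1.75 in colon lines. Glial markers stood at 6.06 ± 0.89 in melanoma lines, above the 4.89 ± 1.44 of CNS lines. These levels were not tested between tissues.

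The test in this part was chosen before its result was seen. A hypothesis was that G2/M transcripts are lower in lines where p53 targets rise. Over lines at 24 h, the G2/M and p53 list means had r = -0.501 at 100 nM (permutation p = 8e-05, adjusted p = 0.00048; rho = -0.421; r = -0.470 without the 2 farthest lines and -0.556 with tissue means removed) and r = -0.394 at 10 nM (permutation p = 0.00168, adjusted p = 0.00448; rho = -0.406; -0.404 and -0.497). This is consistent with the hypothesis and may also follow from other differences between lines, since p53 status was not in the labels and both means share the control array of each line.

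The 3' to 5' difference of beta-actin at 24 h was 0.37 ± 0.13 (SD) at 0 nM, 0.41 ± 0.19 at 10 nM and 0.44 ± 0.28 at 100 nM. IGR-OV1 at 10 nM and 2 h had a response size of 0.706, against a mean of 0.225 over lines, and SK-MEL-2 had 0.655 there. Both arrays were among the 25 of low quality, and their upper quartiles of 7.14 and 7.20 were the lowest of those 25.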
